A study of Mus musculus with 6 samples.

How the data were processed

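Bulk RNA sequencing was carried out on bone marrow-derived macrophages of C57BL/6 mice, cells grown from bone marrow in culture. Per the labels, cells were replated on day 5 of differentiation, transduced on day 6 with an adenovirus carrying a construct named A4.eSPR, and collected on day 8. RNA was isolated with a silica column kit (RNeasy) 48 h after transduction, and 1 µg went into each cDNA library, which Novogene prepared and sequenced. Libraries of 3 untransduced samples and 3 A4.eSPR-transduced samples were compared. What A4.eSPR encodes is not given in the sources used here.

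The authors deposited 1 table with 13401 genes and 1 column of normalized counts per library, a signal scaled by the authors and not a raw count, with the chromosome, start, stop and strand of each gene. Per the submitters' processing notes, Partek, STAR 2.5.3a and DESeq2 were used with the genome build mm10. The role of each tool, the annotation, the counting, its use of strand and any filter are not given in the sources used here, so reads from a gene and from one that overlaps it on either strand may not be separable. Gene positions were compared with GENCODE release M21, which uses GRCm38 (mm10). Of the symbols, 13176 (98.3%) were found there, and 99.5% of those had the same chromosome and start. The stop in the deposited table lies 1 base beyond the GENCODE end, so 1 was taken off it, after which 99.1% of the ends were the same. Positions are counted from 1 and span a whole gene, exons and introns together.

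The low values of each library lie on multiples of a fixed step, the worth of 1 read, which came to 0.764, 1.07 and 0.900 for untransduced replicates 1 to 3 and 1.10, 1.07 and 1.13 for A4.eSPR replicates 1 to 3. Dividing each value by the step gave estimated reads, 26144899, 18786605 and 21913167 in the untransduced libraries and 19673187, 20117639 and 19527638 in the A4.eSPR libraries. Within a tolerance of 0.02 reads that widened in proportion to the value, 74.6% of all values were whole reads. Among values below 50 the share was 73.7% to 75.0% per library. These shares were below the 95% set for calling the reads recovered, and the others were fractions, as where a read is divided between genes. At very high values the tolerance cannot separate whole reads from fractions. A gene with very high values may therefore lack the mark of shared reads used below. Because whole reads were not recovered, a count test was not run on the estimated reads. Of the genes, 8603 (64.2%) had whole estimated reads in all 6 libraries, and genes named in the text that had fractions in 2 or more libraries are described as having shared reads, the reading taken here of a fraction. Every gene in the table had at least 20 estimated reads in at least 1 library, so genes below that level were not analysed here. No column of the table was left unmapped to a sample.

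Values were transformed as log2(value + 1), and genes with a mean of at least 10 over the 6 libraries were kept (13314 genes). The groups were compared with limma's moderated test with a mean-variance trend (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Gene lists of macrophage functions, antiviral responses, other cells that a marrow culture can hold and signs of RNA quality, 38 in all, were written before the data were examined, as were the main test, most of the other settings tried and the rule for named genes. Lists with at least 5 measured members (37 lists) were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists. Tests with an estimated correlation, camera on ranks and fry served as alternatives. Shares of the summed values were compared by a two-sided exact permutation test, which cannot give a p below 0.1 with 3 libraries against 3.

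Named genes are the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 50 and no overlap between the groups, leaving out unnamed gene models. They also include up to 4 members of each list past the threshold with the largest change and the 4 genes with the smallest adjusted p in each direction. Lists of other cells may also be described by their 2 most highly expressed members. One gene that the rule names is not reported here. Genes outside this rule are marked as chosen after their values were seen. Where a group had 0 reads for a gene, the fold is given as a lower bound against a floor of 3 reads over the group. With 1 to 3 reads it is given with a 95% counting interval. Intervals and floors cover counting error only, since reads made by PCR are not independent molecules.

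The test was tried on simulated data with 13294 genes in the same layout of 3 libraries against 3, of which 200 had been changed. It recovered 62.0% of 50 genes changed by 1.25-fold, 86.0% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold. Of its calls, 11 (5.98%) were false, and none (0) of 38 random lists was called. The simulated genes varied independently with a single spread, and few were changed, as many up as down. The trial therefore does not check list calls where genes are correlated, nor the scaling where most genes change. The alternatives for genes numbered 21, of which 18 had been planned. They cover other pseudocounts, filters on low values, scalings between libraries, limma without the trend or with estimated library weights, the replicate number as a block, and each library left out in turn. The 3 added after the data were seen are limma-voom on the estimated reads, genes with whole estimated reads alone, and a rescaling without the 20 genes with the highest mean. The planned edgeR and DESeq2 tests were not run, because whole reads were not recovered.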

Results

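The transcriptomes of 6 samples of C57BL/6 bone marrow-derived macrophages were compared, 3 untransduced and 3 collected 48 h after transduction with an adenovirus carrying A4.eSPR. The comparison addresses how gene expression in macrophages differs after transduction with this vector. No sample given another adenovirus was included, so the response to the virus and the response to the construct were measured together. The labels do not say whether the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The deposited normalized counts summed to 19963612, 20099926 and 19713987 in the untransduced libraries and to 21734452, 21626093 and 22029001 in the A4.eSPR libraries. The estimated sequencing depth was 18786605 to 26144899 reads per library. Values are given as normalized counts, mean ± SD of 3 libraries, and log2 fold changes ± SE compare A4.eSPR with untransduced cells. Where a gene is said to rise or fall by a number, the number is its log2 fold change.

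Most of the genes tested differed between transduced and untransduced macrophages. Of 13314 genes tested, 3941 were higher and 3767 lower after transduction, together 57.9% (limma, adjusted p under 0.05). At an unadjusted p under 0.05 the number was 8257. By at least 2-fold, 1030 genes were higher and 976 lower, and by at least 8-fold 176 were higher and 74 lower. The groups did not overlap in 8423 genes (63.3%), against 10% by chance with 3 libraries against 3. The correlation of log2 values was 0.989 to 0.991 within a group and 0.921 to 0.925 between groups, and the median SD within groups was 0.109 on the log2 scale. The split between higher and lower depended on the scaling between libraries. With the deposited scaling 51.1% of called genes were higher, and with libraries scaled to equal sums 36.1%, which moved the median log2 fold change of all genes from -0.0014 to -0.13. The medians of the gene lists below moved down by about as much with equal sums, so counts and medians of lists with small changes depend on the scaling.

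**Figure D1:**
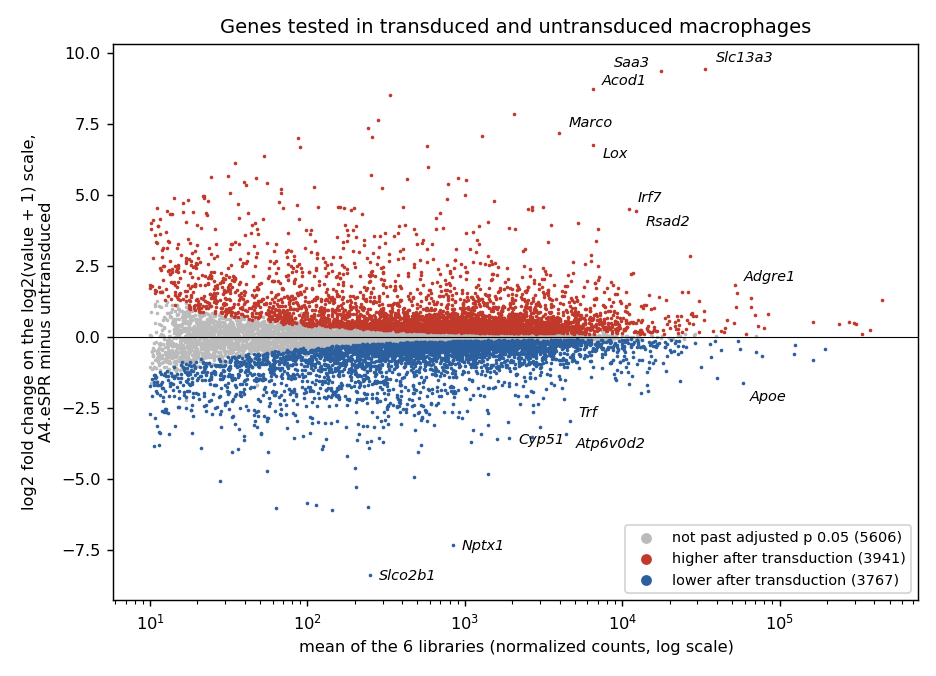
Log2 fold change (vertical axis, A4.eSPR minus untransduced, on the log2(value + 1) scale) of the 13314 genes tested against their mean over 6 libraries (horizontal axis, normalized counts, log scale). Red points are the 3941 genes that were higher and blue points the 3767 that were lower at a limma adjusted p under 0.05, grey points the 5606 others, and the named genes range from Slc13a3 at 9.42 to Slco2b1 at -8.39.

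The largest increase was that of Slc13a3, a sodium-dependent dicarboxylate transporter (chromosome 2, 165405028 to 165473230, minus strand, mm10). Its level rose from 97.7 ± 16.3 to 66822 ± 1615 normalized counts, a log2 fold change of 9.42 ± 0.08 (limma adjusted p = 4.0e-18), and its share of all summed values went from 0.00049% to 0.306%. Saa3, an acute-phase serum amyloid A gene (chromosome 7, 46711998 to 46715700), rose from 52.6 ± 3.08 to 35378 ± 1737 (9.37 ± 0.06, limma adjusted p = 8.0e-20). Acod1, the enzyme that makes itaconate (chromosome 14, 103046977 to 103056573), rose from 32.1 ± 14.1 to 13045 ± 858 (8.72 ± 0.23). The formyl peptide receptor Fpr1 went from 17.2 ± 3.47 to 4082 ± 226, the chemokine Cxcl3 from 1.82 ± 0.31 to 560.2 ± 9.55, and the scavenger receptor Marco from 53.2 ± 2.07 to 7901 ± 421. The NAD-consuming ectoenzyme Cd38, the collagen crosslinking enzyme Lox, Fcrl5 and Raver2 completed the 10 largest increases. Lox reached 12989.6 ± 823 from 121 ± 15.2, with part of its reads shared with other genes. The limma adjusted p of these 10 genes was at most 8.5e-09.

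Among the decreases, the organic anion transporter Slco2b1 (chromosome 7, 99657804 to 99711340) fell from 497 ± 44.3 normalized counts to 0.752 ± 1.30, with 2 estimated reads over the 3 A4.eSPR libraries against 1650 over the untransduced ones, a part of which was shared. The ratio was 669, with a 95% counting interval of 185 to 5530. The neuronal pentraxin Nptx1 (chromosome 11, 119538719 to 119547753) fell from 1666 ± 222 to 9.88 ± 4.23 (-7.33 ± 0.24, limma adjusted p = 2.1e-12). Gpr34, a lysophosphatidylserine receptor, went from 283 ± 31.4 to 3.65 ± 2.68, and Dcstamp, which is needed for fusion of osteoclast precursors, from 223 ± 25.8 to 2.96 ± 1.71. The lipid enzymes Smpd3 and Fads2 were also among the 10 largest decreases, with Tox2, Shisa9 and Ctnnd2. Some of the reads of Smpd3 were shared. Of all genes that were lower, those with the smallest adjusted p were Atp6v0d2, Cyp51, Trf and Hmga2. Transferrin (Trf) fell from 8217 ± 182 to 1056 ± 59.2 and the chromatin protein gene Hmga2 from 5384 ± 434 to 597 ± 8.74, and both shared some reads with other genes.

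**Figure D2:**
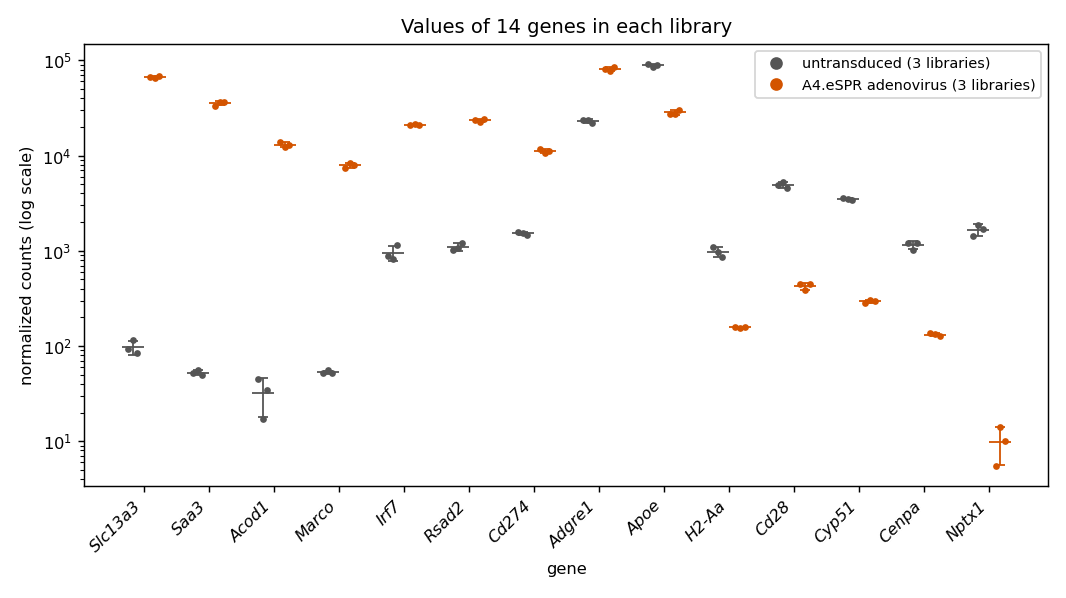
Normalized counts (vertical axis, log scale) of 14 named genes in each of 3 untransduced (grey) and 3 A4.eSPR (orange) libraries, as points, with the group mean and SD as bars. The groups do not overlap in any of the 14 genes, from Slc13a3 (97.7 and 66822) to Nptx1 (1666 and 9.88).

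Interferon-stimulated genes rose almost as a whole. Of 49 measured members of the type I list, 48 were higher and 1 lower, with the same counts adjusted over the list alone, and the median log2 fold change was 1.91 (camera adjusted p = 1.1e-30). With an estimated correlation the list's adjusted p = 0.143. Irf7, a transcription factor of the interferon response, rose from 948 ± 167 to 21114 ± 336 and the antiviral enzyme Rsad2 from 1105 ± 101 to 23411 ± 746, both with some shared reads. Oasl1 and Ifit3 had log2 fold changes of 4.47 ± 0.07 and 3.98 ± 0.08, Ifit3 with shared reads. The exception was Ifi27l2a (-0.30 ± 0.10), named after its value was seen. These genes took 0.330 ± 0.017% of the summed values in untransduced cells and 1.30 ± 0.026% after transduction (exact permutation p = 0.1, the smallest possible).

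Of 26 measured interferon-gamma-associated genes, 23 were higher and 1 lower, also when adjusted over the list alone (median 1.65, camera adjusted p = 4.17e-11). The adjusted p = 0.155 with an estimated correlation. The chemokine Cxcl10 rose from 117 ± 10.99 to 1114 ± 76.6, and Cd274, which encodes the checkpoint ligand PD-L1, from 1528 ± 57.8 to 11181 ± 523, with shared reads in all 6 libraries. The guanylate-binding protein gene Gbp6 rose by 3.90 ± 0.08 with shared reads as well. Ciita, the master activator of MHC class II genes, was the 1 member that fell (-2.75 ± 0.26). In the list of interferons, their receptors and kinases, 8 of 17 members were measured. These changed little, with 3 of 8 higher and 4 lower over all genes and over the list alone (median -0.08, mean 0.05, camera adjusted p = 0.999). Interferon genes were among the members that were not measured. Jak2 rose by 0.78 ± 0.07 on the log2 scale, and Ifngr1 fell by 0.50. Among genes of nucleic acid sensing, 25 of 33 were higher and 3 lower by both adjustments (median 0.69, camera adjusted p = 6.24e-09, adjusted p = 0.212 with an estimated correlation). The sensor Zbp1 rose from 251 ± 28.4 to 3545 ± 25.1, and Ifi206, Ifi205 and Ifi208 rose by 4.78, 3.92 and 3.49, all 3 with shared reads. With genes of whole estimated reads alone, the camera adjusted p of this list was 0.0968.

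Inflammatory mediators and chemokines were also mostly higher. In the list of inflammatory mediators 25 of 30 members were higher and 2 lower, 26 and 2 adjusted over the list alone (median 1.76, camera adjusted p = 3.66e-10). With an estimated correlation the adjusted p = 0.0645. Besides Saa3 and Acod1, the interleukin-12 subunit Il12b had no reads (0) in untransduced cells and 132 over the A4.eSPR libraries, at least 54.2-fold higher, and with this gene at its bound the list's median was still 1.76. Nos2, inducible nitric oxide synthase, rose from 1.32 ± 1.57 to 79.5 ± 11.3 normalized counts. Of 20 chemokines, 16 were higher and 4 lower, the same over the list alone (median 1.46, camera adjusted p = 5.48e-06, adjusted p = 0.134 with an estimated correlation). Cxcl5, Ccl5 and Cxcl1, with log2 fold changes of 5.05, 3.79 and 3.66, followed Cxcl3. In the list of inflammasome and lytic death genes 14 of 23 were higher and 5 lower by both adjustments (median 0.45, camera adjusted p = 0.0176, adjusted p = 0.155 with an estimated correlation). Il1b rose from 30.1 ± 9.16 to 119 ± 0.976, whereas the sensor Nlrp1b fell from 492 ± 91.8 to 148 ± 32.9. With genes of whole reads alone this list had a camera adjusted p of 0.264.

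MHC class I genes mostly rose and class II genes mostly fell. Of 26 class I presentation genes 22 were higher and 2 lower, 23 and 2 adjusted over the list alone (median 0.95, camera adjusted p = 3.66e-10). With an estimated correlation the adjusted p = 0.0835. H2-T24 rose from 344 ± 17.6 to 2462 ± 75.6. H2-Q6, H2-Q7 and H2-T10, whose reads were shared with other genes and whose values are uncertain, rose by 3.65, 3.32 and 2.44. Of 13 class II genes 9 were lower and 1 higher, 10 and 1 adjusted over the list alone (median -0.42, camera adjusted p = 2.96e-03, adjusted p = 0.23 with an estimated correlation). H2-Aa fell from 972 ± 114 to 157 ± 1.20, H2-Eb1 from 688 ± 59.98 to 118 ± 10.8 and the invariant chain Cd74 from 4149 ± 245 to 1090 ± 58.8. The list of costimulation and checkpoint ligands went both ways, with 9 of 20 higher and 6 lower, 10 and 6 over the list alone (median 0.34, camera adjusted p = 0.173). Siglec1 rose by 2.09 ± 0.08 with shared reads, Tnfsf15 rose by 1.93 ± 0.39, and Cd83 fell by 2.09 on the log2 scale.

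Proliferation genes and cholesterol biosynthesis genes fell. Of 43 proliferation genes 42 were lower and none (0) higher by both adjustments, with a median of -2.07 (camera adjusted p = 1.94e-25). The adjusted p = 0.0835 with an estimated correlation. The cyclin Ccnb2 went from 543 ± 13.0 to 62.5 ± 24.9, the centromere gene Cenpa from 1150 ± 106 to 132 ± 4.22 and Cenpf from 584 ± 40.5 to 69.6 ± 12.9. Stmn1 fell by 3.09 with shared reads in all libraries. Ccne1 was the member that did not pass (0.12 ± 0.09), named after its value was seen. All 24 measured cholesterol biosynthesis genes were lower, also over the list alone, with a median of -2.18 (camera adjusted p = 1.79e-18), and the adjusted p = 0.111 with an estimated correlation. Cyp51, the lanosterol demethylase (chromosome 5, 4081145 to 4104746), fell from 3522 ± 96.9 to 294 ± 11.98, Hsd17b7 from 880 ± 19.6 to 90.0 ± 20.8, and Idi1, with shared reads, from 2972 ± 150 to 243 ± 30.6. Genes of cholesterol efflux and lipid handling moved both ways, 10 of 23 higher and 11 lower by both adjustments (median -0.08, camera adjusted p = 0.999). Nr1h3, which encodes the oxysterol receptor LXR alpha, rose from 776 ± 12.7 to 2556 ± 64.2. Apoe, Fasn and Scd1 fell by 1.64, 1.69 and 1.79 on the log2 scale.

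**Figure D3:**
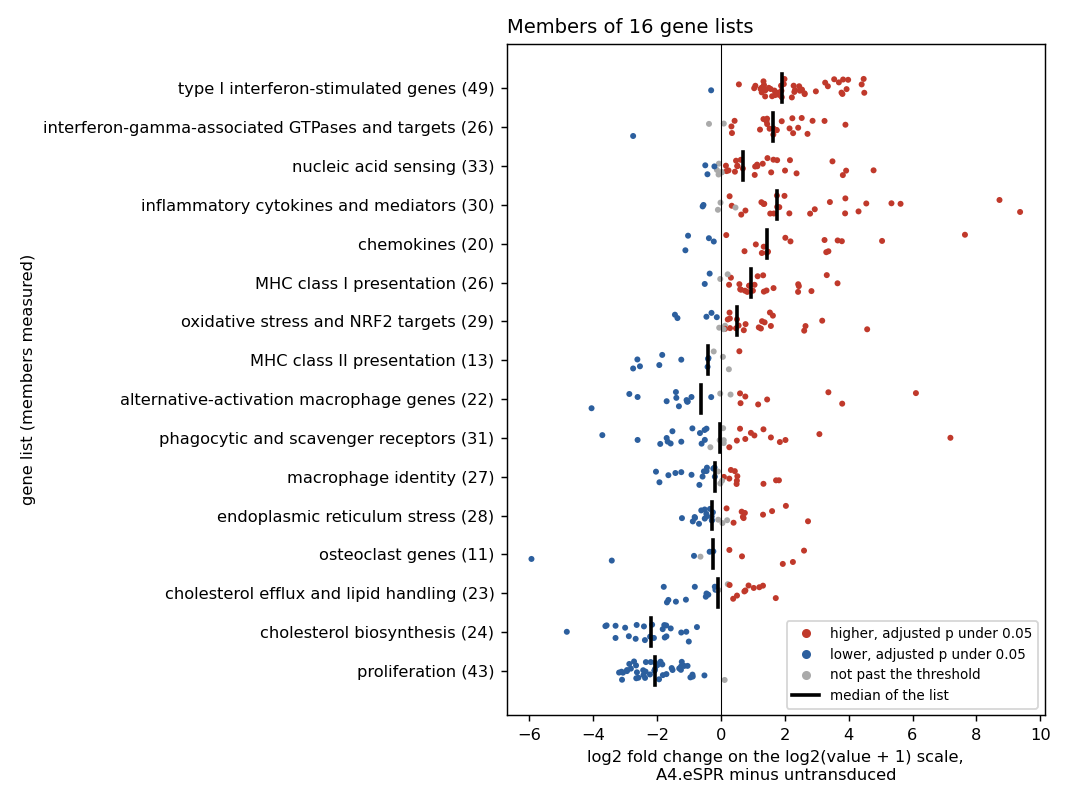
Log2 fold changes (horizontal axis, A4.eSPR minus untransduced, log2(value + 1) scale) of the measured members of 16 gene lists (vertical axis, number measured in brackets), each point a gene and each black bar the list's median. Type I interferon-stimulated genes have a median of 1.91 and cholesterol biosynthesis and proliferation genes medians of -2.18 and -2.07, while macrophage identity and phagocytic receptor genes lie on both sides of 0.

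Lists of macrophage identity and function held genes that moved both ways. Of 27 identity genes 10 were higher and 14 lower (median -0.19, camera adjusted p = 0.308), and with quantile normalization 8 were higher and 17 lower (median -0.30, camera adjusted p = 0.0279). Adgre1, which encodes F4/80, rose from 23058 ± 980 to 81295 ± 3962 with some shared reads and Aif1 from 662 ± 17.8 to 2194 ± 75.9, while the chemokine receptors Ccr2 and Cx3cr1 fell by 2.03 and 1.92 on the log2 scale. Among 31 phagocytic and scavenger receptors 12 were higher and 14 lower (median -0.04, mean 0.05, camera adjusted p = 0.739). Clec4e rose by 3.08 ± 0.07, Itgax (CD11c) fell from 2021 ± 97.4 to 154 ± 21.8, and Cd163 fell from 38.9 ± 14.5 to 6.18 ± 4.28. Alternative-activation genes were higher in 8 and lower in 12 of 22 cases (median -0.61, camera adjusted p = 0.573). Egr2 fell from 954 ± 88.3 to 56.6 ± 3.58, and Ccl22 and Arg1 rose by 3.37 ± 0.19 and 3.80 ± 0.65. Cd209f had no reads (0) in untransduced cells and 189 after transduction, partly shared, at least 77.7-fold higher, and with it at its bound the median stayed at -0.61. Of 18 genes whose products supply signalling parts of chimeric receptors, 7 were higher and 8 lower (median -0.09, camera adjusted p = 0.315). Cd28, a costimulatory receptor, fell from 4931 ± 368 to 427 ± 35.8, and Axl and Clec7a fell by 1.90 and 1.67, while Il4ra rose by 1.45 ± 0.04 with some shared reads. The counts of these 4 lists were the same adjusted over the list alone.

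Lysosomal genes were higher in 21 and lower in 11 of 36 cases by both adjustments (median 0.26, camera adjusted p = 0.0401, adjusted p = 0.751 with an estimated correlation). The call was lost without untransduced replicate 3 (adjusted p = 0.0572), with quantile normalization (0.763), without the 20 highest genes (0.118), with whole-read genes alone (0.403), with genes of a mean of at least 100 (0.0591), without the limma trend (0.0843) and with camera on ranks (0.0647). With quantile normalization 16 of the 36 genes were higher and 14 lower (median 0.0055), so the rise of the list depends on the method. Ctsz rose from 18258 ± 326 to 43622 ± 724 and Ctsk by 1.94 ± 0.09, whereas Tfeb, a regulator of lysosome biogenesis, fell by 1.21 and Atp6v0d2, a proton pump subunit, fell from 8091 ± 192 to 758 ± 43.3. Osteoclast genes split, 5 of 11 higher and 5 lower over all genes and over the list alone, with a median of -0.24, a mean of -0.34 and an upward camera test (adjusted p = 0.964). Acp5 and Mmp9 rose by 2.60 ± 0.07 and 2.25 ± 0.09, against the falls of Dcstamp and Atp6v0d2. Matrix enzymes and adhesion genes were higher in 12 and lower in 15 of 28 cases by both adjustments (median -0.29, mean 0.03, camera adjusted p = 0.332). The integrin Itgal rose from 511 ± 70.9 to 4330 ± 477 and Mmp14 from 1092 ± 43.5 to 5389 ± 140, and urokinase (Plau) fell from 21075 ± 806 to 5286 ± 428 with some shared reads. Complement genes were higher in 9 and lower in 9 of 19 cases by both adjustments (median 0.49, camera adjusted p = 0.761). Cd55 rose by 5.52 ± 0.14, Cfb by 6.71 ± 0.27 with shared reads, and C1s1 by 3.43 ± 0.70, while Itgax, also in this list, fell by 3.71.

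Oxidative stress and NRF2 target genes were higher in 21 and lower in 5 of 29 cases, the same over the list alone (median 0.50, camera adjusted p = 1.32e-06, adjusted p = 0.143 with an estimated correlation). In the rescaling without the 20 highest genes 16 of 26 were higher and 5 lower (median 0.30). The cystine transporter gene Slc7a11 rose from 212 ± 21.4 to 5115 ± 712 and Sod2 from 1741 ± 38.8 to 10929 ± 276, both with shared reads, and Gsta3 and Nqo1 rose by 3.17 ± 0.12 and 2.61 ± 0.13. Endoplasmic reticulum stress genes were higher in 10 and lower in 15 of 28 cases, 11 and 15 over the list alone (median -0.27, mean 0.10, camera adjusted p = 0.394). The 4 largest changes of this list were rises. Trib3 rose from 163 ± 19.1 to 1086 ± 125, Ddit3 (CHOP) from 480 ± 13.6 to 1971 ± 81.8, and Ppp1r15a and Chac1 by 1.60 and 1.32. Apoptosis and p53 target genes were higher in 21 and lower in 7 of 35 cases, 21 and 9 over the list alone (median 0.32, camera adjusted p = 0.0465, adjusted p = 0.305 with an estimated correlation). This call was lost without untransduced replicate 3 (adjusted p = 0.0572) or A4.eSPR replicate 2 (adjusted p = 0.0897), with quantile normalization (0.0725), estimated sample weights (0.0585), whole-read genes alone (0.195), genes of a mean of at least 100 (0.12) and without the limma trend (0.061). With equal sums 17 were higher and 12 lower (median 0.19). Fas rose from 51.6 ± 3.55 to 185 ± 14.6, Mdm2 by 0.78 ± 0.04 and Bcl2a1a by 4.13 ± 0.34, the last 2 with shared reads, and Sesn1 fell by 1.95 with some shared reads.

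Glycolysis genes were higher in 13 and lower in 5 of 23 cases, 14 and 5 over the list alone (median 0.20, camera adjusted p = 0.105). With equal sums 8 were higher and 7 lower (median 0.07), and with quantile normalization 9 and 7 (median 0.05). Egln3, Pfkfb3 and Hk2 rose by 2.62 ± 0.20, 1.55 ± 0.05 and 1.19 ± 0.05, and Pdk1 fell by 1.76. Of 36 nuclear genes of oxidative phosphorylation 11 were higher and 4 lower by both adjustments (median 0.06, camera adjusted p = 0.275), the largest rise being that of Cox5a (0.85 ± 0.07). With equal sums 6 were higher and 9 lower (median -0.07), and in a rescaling without the 20 highest genes 8 and 8 (median -0.03). Heat shock genes were higher in 6 and lower in 4 of 15 cases by both adjustments (median 0.08, camera adjusted p = 0.808), but in 3 and 6 with equal sums (median -0.05), 4 and 5 with upper quartiles and 3 and 5 without the 20 highest genes (median -0.01). Hspa1a, which shares its reads with a near-identical gene, rose by 1.39 ± 0.16, and Bag3 fell by 0.49. Immediate-early genes were higher in 7 and lower in 11 of 20 cases, 9 and 11 over the list alone (median -0.15, camera adjusted p = 0.67), with falls of Egr1 from 827 ± 65.5 to 120.4 ± 10.7, of Egr3 by 2.72 and of Fosb by 3.14.

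Members of the lists of other cells and of RNA quality also passed the threshold, as did 57.9% of all genes tested. Among the lists of other cells, only that of neutrophil genes was called. Neutrophil genes were higher in 10 and lower in 5 of 15 cases by both adjustments (median 0.80, camera adjusted p = 0.0201, adjusted p = 0.267 with an estimated correlation). The call was also lost without the limma trend (adjusted p = 0.057), with whole-read genes alone (0.0703) and with camera on ranks (0.0675). The granule enzyme genes Mpo, Prtn3 and Ctsg rose, Mpo from 149 ± 3.18 to 1896 ± 51.0 with some shared reads, and Retnlg fell by 3.36. The most highly expressed members were Mmp8 (2101 ± 34.0 and 2321 ± 139) and Ngp (1984 ± 60.1 and 1706 ± 153). Among 7 B cell genes 4 were higher and none (0) lower, 6 and 0 over the list alone (median 1.49, camera adjusted p = 0.0986, 0.039 without the limma trend). Ms4a1 had 3 and 86 reads in the groups (ratio 35.3, 95% counting interval 11.7 to 174.7) and Pax5 1 and 62 (ratio 76.4, interval 13.2 to 3067). The abundant members Blnk and Ighm had log2 fold changes of 0.11 ± 0.05 and -0.17 ± 0.12, neither past the threshold. Dendritic cell genes were higher in 2 and lower in 3 of 6 cases (median -0.11, mean 0.14, camera adjusted p = 0.964), with Bst2 at 2.47 ± 0.04 and Tcf4 at -0.19 ± 0.06. Of 3 T and NK cell genes, too few for the list test, Il7r rose by 0.77 ± 0.04, with some shared reads, while Lat and Cd4 fell by 2.44 and 0.99. Erythroid and megakaryocyte genes were higher in 4 and lower in 2 of 6 cases (median 0.70, camera adjusted p = 0.75), but in 2 and 2 with equal sums, with Ppbp at 1.34, and Vwf fell from 1723 ± 73.1 to 818 ± 37.9. Of 5 mast cell, basophil and eosinophil genes 2 were lower and none (0) higher (median -0.60, camera adjusted p = 0.235), namely Ccr3 and Kit. Fibroblast, stromal and endothelial genes were higher in 3 and lower in 9 of 15 cases (median -0.89, camera adjusted p = 0.152). Col1a1 fell from 208 ± 14.7 to 55.4 ± 7.07 and Postn by 3.39, and Dcn rose from 10.2 ± 5.37 to 101 ± 15.8. Counts in these last 5 lists were the same adjusted over the list alone.

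Mitochondrially encoded transcripts were lower in 11 and higher in 3 of 15 cases by both adjustments (median -0.43, camera adjusted p = 0.111). The camera adjusted p was 0.0359 without untransduced replicate 2 and 0.0261 with the replicate number as a block. Within that list the ribosomal RNAs mt-Rnr1 and mt-Rnr2 rose by 2.03 ± 0.07 and 1.27 ± 0.08, while the messenger RNA mt-Cytb fell from 14266.5 ± 2747 to 6774 ± 223. Together these transcripts took 0.833 ± 0.153% of the summed values in untransduced and 0.740 ± 0.042% in A4.eSPR libraries (exact permutation p = 0.5). Cytosolic ribosomal protein genes were lower in 28 and higher in 6 of 85 cases, 26 and 5 over the list alone (median -0.14, camera adjusted p = 0.0176, adjusted p = 0.762 with an estimated correlation). That call was lost without A4.eSPR replicate 1 (adjusted p = 0.131) and with fry (0.111), and with whole-read genes alone the test pointed up (0.923). The counts depend on the scaling, with 52 lower and 2 higher with equal sums (median -0.27) and 46 and 3 without the 20 highest genes (median -0.24). The nuclear ribosomal RNA row CT010467.1, chosen after its value was seen, took 1.11 ± 0.060% and 0.762 ± 0.166% of the summed values (exact permutation p = 0.1). Replication-dependent histone genes were higher in 15 and lower in none (0) of 17 cases by both adjustments (median 1.58, camera adjusted p = 7.52e-04, adjusted p = 0.119 with an estimated correlation). The adjusted p was 0.0521 among genes with a mean of at least 100. H3c4 rose from 20.8 ± 1.46 to 91.7 ± 12.4 and H2bc11 from 6.69 ± 7.28 to 29.9 ± 4.62, both low and with shared reads.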

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

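The tests added after the data were seen were limma-voom on estimated reads, genes with whole estimated reads alone, and the rescaling without the 20 highest genes. The planned edgeR and DESeq2 tests were not run, because 74.6% of the values came out as whole reads. Of the 164 named genes, 162 passed the threshold in the main test. Of 3356 results of named genes under the alternatives, 3332 kept their direction and side of the threshold, 21 lost the call, 3 gained one and none (0) reversed. The changes fell on 8 genes, Mmp8, Rps3a3, Tcf4, Ifngr2, Ngp, H2ac7, Blnk and Ighm, of which Rps3a3 and H2ac7 had shared reads. Of 882 list results, 825 were unchanged, 38 lost a call, 15 gained one and 4 reversed. Called genes numbered 7708 in the main test and 6945 to 7711 when 1 library was left out, and 7751 with limma-voom, which kept 99.4% of the main calls. The numbers higher and lower were 3941 and 3767, and 1030 and 976 with a fold of at least 2, where the added condition on size is the cause. Lists called higher and lower were 12 and 4. They were 0 and 0 of 37 with an estimated correlation, which allows for the correlation of a list's genes within the groups. That estimate was 0.359 for type I interferon-stimulated genes. It was -0.0115 for inflammatory mediators, -0.00774 for replication-dependent histones and -0.028 for inflammasome genes, below the preset 0.01. A stronger correlation therefore does not account for the loss of the calls for mediators, histones and inflammasome genes. The setting thus changes more than the correlation, and its adjusted p-values, here and with each list, do not measure the effect of correlation alone. With fry, which tests each list by itself and not against other genes, 19 lists were called higher and 10 lower. With whole-read genes alone 6 lists were called higher of 35 tested, with fewer members each. With an estimated correlation the adjusted p was 0.143 for type I interferon-stimulated genes, 0.155 for interferon-gamma-associated genes, 0.0645 for inflammatory mediators, 0.0835 for proliferation and 0.111 for cholesterol biosynthesis. In each of the other alternatives these 5 lists kept their calls. Opposite directions came from fry for phagocytic receptors (adjusted p = 6.87e-03), cholesterol efflux (0.0181) and dendritic cell genes (8.13e-03), lists not called in the main test, and from whole-read genes for ribosomal proteins (0.923). The cause was not tested.

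The share of called genes that were higher was 51.1% with the deposited scaling, 49.9% with trimmed means, 48.3% with quantiles, 44.1% with upper quartiles, 40.0% without the 20 highest genes and 36.1% with equal sums. Equal sums moved the median log2 fold change of all genes by -0.13 and the sign of 26 main calls, so changes smaller than that depend on the scaling. Calls for the lysosome, apoptosis and ribosomal protein lists depended on single libraries and, like that for neutrophil genes, on other settings, as given with their values, and the histone list had an adjusted p of 0.0521 among genes with a mean of at least 100. No effect common to samples with the same replicate number was visible, which does not exclude that they came from the same animal or culture. Deviations from the group means correlated at 0.0025, -0.027 and -0.0015 between samples with the same number, and not every sample correlated best with its own number. With the number as a block 7605 genes were called, and 97.3% of the main calls were kept. The block changed 1 list, the mitochondrial transcripts, to an adjusted p of 0.0261. The estimated depth of 18786605 to 26144899 reads leaves genes such as Slco2b1, Il12b and Pax5 at a few reads in 1 group, where folds have wide intervals.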

Other observations

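The test for mature neutrophils, the families of genes sharing a name and the scaling of the Slfn and Rgs families were chosen after the results had been seen. Families of genes that share the letters before the number were tested with camera as a further description, 284 families with at least 6 measured members, of which 8 were called higher and 3 lower. None (0) was called with an estimated correlation (adjusted p = 0.997), while the preset correlation gave the following values. Called higher were Ifi, Ifit, Oas, Gbp, Slfn, Ccl, Cxcl and Parp, and lower Mcm, Cdca and Rgs, with camera adjusted p from 1.65e-05 (Ifi) to 0.0441 (Cxcl and Parp). Slfn and Rgs, not those with the smallest p, were picked for description after their values were seen. In the Schlafen family (Slfn), which has been linked to growth control and to restriction of viruses, 7 of 8 genes were higher and 1 lower (median 1.61, camera adjusted p = 4.44e-03), and Slfn5 and Slfn8, both with shared reads, also belong to the interferon list. Slfn4 rose from 38.2 ± 17.6 to 1779 ± 185 normalized counts and Slfn1 from 32.7 ± 8.06 to 778 ± 49.2, and Slfn2 was 2.81-fold higher. In the family of regulators of G protein signalling (Rgs), 9 of 11 genes were lower and 1 higher (median -1.07, camera adjusted p = 4.52e-03). Rgs2 fell from 6974 ± 268 to 1529 ± 96.3, Rgs16 from 237 ± 12.5 to 16.1 ± 5.84 and Rgs10 from 1992 ± 73.7 to 599.6 ± 51.6. The 1 higher Rgs gene no longer passed with upper quartiles, equal sums, quantiles or without the 20 highest genes.

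Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 7708 called genes and the highest of the others 0, so 1 split gave as many. With 10 splits no share under 0.05 can be reached. Every other split mixes libraries of both groups, so a large difference between the groups enters the spread within each set. The 0 calls of those splits are therefore no evidence on chance.

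The first pattern is the rise of the azurophil granule genes Mpo, Elane, Prtn3 and Ctsg, Mpo from 149 to 1896 and Elane, chosen after its value was seen, from 87.3 to 727. All 15 measured neutrophil genes had a mean of at least 10 in untransduced cells too, and 2 stand in another list. Reads shared with other genes are argued against, since 22 of the 24 estimates for these 4 genes were whole reads. Mature neutrophils cannot be judged from 6 genes chosen after the results were seen. The median log2 fold change of those 6 genes was -0.350 ± 0.783 (SE), below the 3.62 to 3.75 of Prtn3, Mpo and Ctsg, a range without Elane. The SE of this median and of those below measures the spread between genes, which are not independent, and not between libraries. Among the 6 genes S100a8 (1.00) and S100a9 (0.48) were higher and 4 lower (Ltf -1.08, and Retnlg -3.36 from only 21.3 normalized counts). S100a8, S100a9, Ngp and Ltf stood at 742, 1367, 1984 and 1015 normalized counts in untransduced cells. A gain of mature neutrophils may therefore not show in them as a large fold. Camp and Retnlg stood lower, at 113 and 21.3, and both fell. A contribution of mature neutrophils stays open. Granulocyte precursors in the transduced cultures may have contributed and stay open: 19 of their other genes had a median of 0.797 ± 0.456. Of these, 12 were higher (Ms4a3 3.04, Hp 2.91, Plac8 2.79, Muc13 2.56, Gfi1 1.78, Myb 1.24) and 5 lower (Sox4 -2.81, Kit -0.81, Anxa1 -1.22, with shared reads). The lower genes Anxa1, Clec5a and Sox4 already stood at 26631, 859 and 569 normalized counts in untransduced cells, so a gain of precursors may not show in them. Their high level does not account for their falls, however. Kit and Serpinb1a fell from lower levels, 105 and 158 normalized counts, to 58.9 and 102. Cd34, at 32.3 and 23.2, did not pass the threshold. A response of the macrophages themselves stays open, untested.

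The second pattern is the rise of replication-dependent histone transcripts while proliferation genes fell. A higher share of RNA without a poly(A) tail could account for it, and 6 such RNAs had a median log2 fold change of 0.582 ± 0.562 (SE), with mt-Rnr1 (2.03) and mt-Rnr2 (1.27), which carry short tails at most, higher and CT010467.1 (-0.43) and Rn7sk (-0.99) lower. Reads divided between near-identical histone genes could also matter, and only 1 measured histone gene, H2bc21, had whole reads in all 6 libraries (-0.275 ± 0.129). Neither of these can be told apart from a change in the cells, because the RNAs went both ways and 1 gene is too few.

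The third pattern is the rise of the B-lineage genes Ms4a1, Pax5 and Cd79a from almost no reads. Of the 7 measured B cell genes, 4 had a mean of at least 10 in untransduced cells and none (0) stands in another list. Reads shared with other genes are argued against, since 18 of 18 estimates were whole. B cells in the transduced cultures may have contributed and stay open: 14 other B cell genes had a median of 0.318 ± 0.630 (SE), 6 higher (Pou2af1 4.12, Spib 2.11, Cd22 1.40) and 5 lower (H2-Aa -2.61, Cd74 -1.93, Bank1 -1.12). Besides Bank1, the lower ones were the class II presentation genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1. These stood at 4149, 972, 915 and 688 normalized counts in untransduced cells and fell with the class II list. Their fall therefore says little about B cells, and the set decides nothing here. Ighm, at 365 and 324 normalized counts, did not pass the threshold.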
